A study of Mus musculus with 6 samples.

How the data were processed

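RNA-seq libraries of DC2.4, a mouse dendritic cell line, and of its derivative with the PD-L1 gene knocked out were analysed, 3 libraries per group. Per the labels' protocols, RNA was taken up in TRIzol and libraries were made from total RNA with a KAPA Hyper Prep kit. The submitters' processing notes name Trimmomatic 0.39 (read trimming), STAR 2.7.5c (alignment) and StringTie 2.1.7 (transcript assembly and quantification) with the mouse genome build mm10, without saying which step each was used for. The values deposited by the authors are whole-number read counts per gene, not scaled, with column totals that differ between libraries. The counting step, the annotation release and the strand setting are not given in the sources used here. Reads of a gene and of an antisense or overlapping partner can therefore not be separated, and reads of near-identical copies (class I MHC genes, ribosomal protein genes and their pseudogenes, ferritin genes, Ly6 and Cyp3a genes) may have been split or dropped.

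Each column was matched to its sample by name, and groups and replicate numbers came from the sample labels. No label says that the libraries of a group came from separate cultures or that the knockout line came from a single clone, so p-values measure the spread between these libraries, which may be technical. No pair of libraries held the same values: counts of libraries within a group differed by more than sampling noise.

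The table held 31205 genes, of which 18546 had a count in any library. Genes were filtered with edgeR's filterByExpr, which left 11453, and totals were scaled by TMM factors. The test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) of knockout against control, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 17.5%. CPM values are TMM-normalized, given as mean ± SD with n = 3. Log2 fold changes are knockout minus control, and SE is their standard error. Genes at 0 counts in all knockout libraries are given as at least N-fold lower, against a floor of 3 counts over the group; genes with 1 to 3 counts have the ratio with a 95% counting interval. Floors and intervals cover counting error only.

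Before the data were examined, 28 gene lists were fixed, with the rule for naming genes: Cd274, 8 ferroptosis genes whatever their result, up to 4 called members per list with non-overlapping groups and the lowest adjusted p, and the 10 largest folds up and 10 down among called genes with a mean log2 CPM of at least 2, non-overlapping groups and a symbol that is not of a predicted gene. Lists were tested with limma's camera on log2 CPM at a preset inter-gene correlation of 0.01, adjusted over the 27 lists with tested members. An estimated correlation and fry were run beside it. Fry asks whether a list's genes move, on balance, one way, without comparing them with other genes. No list was chosen from these libraries. Some genes that the naming rule selects are not reported here.

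Gene positions, exon lengths and GC content came from a GENCODE annotation of the same build. Of the 31205 symbols, 30194 matched directly and 313 through another symbol, 698 did not match and 52 named more than 1 gene. Of the tested genes, 99.3% had a length and GC content.

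Settings varied were DESeq2 size factors, upper quartile and total-count scaling, no filter on low counts and a filter of 1 CPM in 3 libraries, DESeq2 1.42.0 (Wald test), limma-voom, the replicate number as a block, glmTreat against a 1.5-fold change, and leaving out each library. Offsets that remove each library's trend with exon length and GC content (loess, span 0.3), alone, with the block, or with each library's chromosome medians, were added after the data were seen.

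The steps were tested on simulated counts drawn from the means and totals of these libraries. With 200 genes changed, of which 99 of each size were tested, the edgeR test called 81.82% of those at an absolute log2 change of 1 and 95.96% at 2, among 11295 genes tested, and 9.28% of its 194 calls were genes that had not been changed. A shift of 0.4 put into chromosome 17 beside a length trend came back as 0.41 after the length and GC correction, over 11338 genes. Camera called the raised list in a simulation over 11298 genes and none of the 26 others (0 called). Genes were drawn independently there, so it could not test list calls where genes move together. In these libraries the estimated inter-gene correlation ranged from -0.178 (stromal and fibroblast markers) to 0.701 (ATF4 and amino acid response).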

Results

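The data compare gene expression in DC2.4 cells, a mouse dendritic cell line, with that in its PD-L1 knockout derivative. PD-L1, encoded by Cd274, is the ligand of the T cell checkpoint receptor PD-1. The series title places the comparison in the study of PD-L1 and dendritic cell ferroptosis, an iron-dependent death by lipid peroxidation, during immunogenic chemotherapy. The labels name no drug treatment of these 6 libraries. Control libraries 1, 2 and 3 held 10918498, 15909256 and 23250065 counts. Libraries 1, 2 and 3 labelled knockout held 13501776, 16323812 and 21133688. On log2 CPM, the first principal component held 66.3% of the variance and separated the groups, with controls between -45 and -34.9 and knockouts between 20.9 and 51.2. The second held 15.8% and set knockout library 1 (38) apart from knockout libraries 2 and 3 (-10.9 and -15.6).

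Cd274 (ENSMUSG00000016496.7, chromosome 19, 29367455 to 29388095, mm10) was not lower in the libraries labelled knockout. It had 52, 99 and 171 counts in control libraries 1, 2 and 3 and 102, 81 and 163 in knockout libraries 1, 2 and 3. This gave 5.78 ± 1.09 CPM in control and 7.08 ± 1.44 in knockout (SD, n = 3), a log2 fold change of 0.28 (SE 0.25, 95% interval -0.27 to 0.83, edgeR adjusted p = 0.415). Counts per gene do not show a change within the coding sequence, so the transcript level does not check the knockout label, and every direction given here rests on the labels. Of 11 tested genes of the fixed list of neighbours of Cd274, Plgrkt was higher (log2 fold change 0.66, SE 0.15) and Jak2, a cytokine receptor kinase, was lower (-0.94, SE 0.16). That left 9 without a call, adjusted over the list alone as well (1 higher, 1 lower), and the list was not called (camera adjusted p = 0.626).

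Cells labelled knockout had lost transcripts of a set of genes almost completely. Creb5, a CREB-family transcription factor (chromosome 6, 53287270 to 53700376), fell from 795 ± 73.5 CPM in control to 8.79 ± 1.05 in knockout (log2 fold change -6.49, SE 0.18, edgeR adjusted p = 7.15e-08). Igf1, a growth factor, fell from 98.3 ± 2.56 to 1.16 ± 1.43 CPM. Met, the hepatocyte growth factor receptor (10.2 ± 4.49 CPM in control), Atp10a (9.11 ± 2.11) and the adhesion molecule Nectin3 (8.76 ± 0.63) had 0 counts in all 3 knockout libraries, and were at least 164-fold, 146-fold and 141-fold lower against the floor. The largest rise among genes meeting the naming rule was that of Mkln1os, an antisense transcript that cannot be separated from overlapping genes here (1.05 ± 0.21 to 7.13 ± 4.88 CPM). Its rise lay mostly in knockout libraries 2 and 3 (10.3 and 9.60 CPM), with 1.51 in knockout library 1 and 1.19 in the highest control. The next largest was that of Gdf15, a stress-induced cytokine, from 21.3 ± 6.32 to 69.4 ± 4.33 CPM (log2 fold change 1.69, SE 0.21, edgeR adjusted p = 0.00105).

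Of the 11453 genes tested, 1353 were higher and 1543 lower (25.3%), and 4680 had an unadjusted p under 0.05. At 2-fold or more, 90 were higher and 693 lower. At 8-fold or more, 1 was higher and 140 were lower. The single riser was Clec4a3, a C-type lectin, at a log2 fold change of 3.61 (SE 0.50), named after its value was seen. By a rule set on the data (at least 2 CPM in every control library and less than an eighth of the lowest control in every knockout library), 54 genes were nearly lost, all of them called, and 0 were gained by the mirrored rule. Groups did not overlap for 43% of genes, where chance gives 10%. The other largest falls were those of Sgk3 (-6.30), Oxr1 (-5.96), Ncs1, Fmnl2 and Mid1ip1. Ncs1, with 1 count in all knockout libraries, had a control-to-knockout ratio of 469 (84.1 to 18510), Fmnl2, with 3 counts, of 203 (69.5 to 986), and Mid1ip1, with 2 counts, of 194 (53.6 to 1600). The other largest rises were those of Ddit3 (1.67), Arhgdig (1.63), Cyfip2 (1.55), Morn2 (1.52), Scmh1 (1.52), Cyp3a16 (1.51), Sdhaf4 (1.47) and Ier3 (1.43). Knockout library 1 was the highest for Ddit3 (39.9 CPM, against 13.6 and 16.5 in knockout libraries 2 and 3) and Cyfip2 (26.9, against 8.66 and 9.80). Without it their log2 fold changes were 1.04 and 0.84, both still called. Ddit3 was not called without control library 2 (adjusted p = 0.0528), nor Cyfip2 without control library 1 (0.0605), 2 (0.0746) or 3 (0.0599). Ier3 had 57.5 CPM in knockout library 1 and 56.3 in control library 3, against 143 and 153 in knockout libraries 2 and 3.

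**Figure D1:**
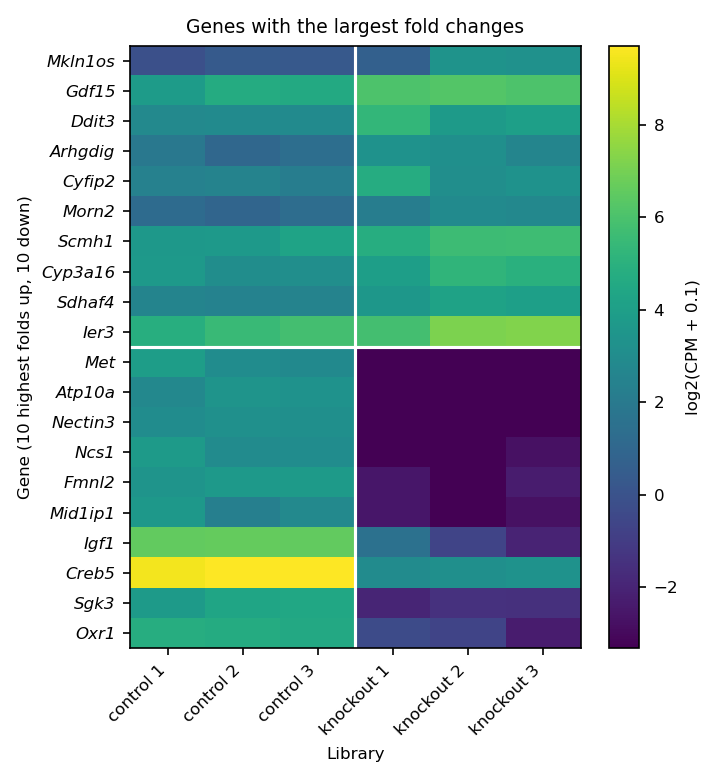
Heat map of log2(CPM + 0.1) for the 10 genes with the largest fold up and the 10 with the largest fold down (rows) in each of the 6 libraries (columns). Met, Atp10a and Nectin3 are at 0 CPM in all 3 knockout libraries, and Creb5 goes from a mean of 795 to 8.79 CPM.

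The count of calls depended on single libraries: without control library 2 it was 166 higher and 472 lower, and without knockout library 1 it was 2346 and 2616. Scaled by total counts alone, which moved the median log2 fold change of all genes to -0.14, 667 genes were higher and 2212 lower, so that 23.2% of calls were higher in place of 46.7%.

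Of the ferroptosis genes, the glutathione peroxidase Gpx4, which reduces lipid peroxides (chromosome 10, 80047166 to 80056439), was higher in knockout, at 238 ± 16.6 against 160 ± 15.8 CPM (log2 fold change 0.58, SE 0.13, edgeR adjusted p = 0.0142). So was Slc3a2, the heavy chain of the cystine transporter (chromosome 19, 8706882 to 8723369), at 431 ± 104 against 265 ± 41.7 CPM (0.70, SE 0.19, adjusted p = 0.0247). Slc7a11, the transporter's light chain (chromosome 3, 49892526 to 50443614), did not pass the test (63.0 ± 43.2 against 47.0 ± 2.49 CPM, 0.42, SE 0.37, adjusted p = 0.42): knockout library 1 alone was high, at 113 CPM, with 42.0 and 34.3 in the other knockout libraries. Acsl4, which makes oxidizable phospholipid precursors (-0.21, adjusted p = 0.255), the transferrin receptor Tfrc (-0.11, 0.693), the ubiquinone reductase Aifm2 (0.04, 0.877), Hmox1 (-0.24, 0.576) and the ferritin heavy chain Fth1 (0.02, 0.945) did not pass either. Hmox1 was called in 1 alternative, lower after the length and GC correction with the replicate block (-0.60, adjusted p = 0.0136), but not without the block (-0.58, 0.171). Gpx4 was not called without control library 2 (0.51, adjusted p = 0.0901) or knockout library 3 (0.52, 0.0616), nor after the length and GC correction (0.26, 0.127). Slc3a2 was not called without control library 2 (0.64, adjusted p = 0.114) or 3 (0.64, 0.0767), with total counts alone (0.56, 0.0573) or with length, GC and chromosome medians removed (0.54, 0.077).

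Among 22 tested genes of ferroptosis defence, 7 were higher and 1 lower (7 and 1 adjusted over the list alone), including the mitochondrial iron-sulfur protein Cisd1 (0.65, SE 0.16), the peroxidase Prdx6 (0.54, SE 0.14) and the ferritin light chain Ftl1 (0.50, SE 0.13). After the length and GC correction 3 of the 22 were higher, and neither Cisd1 (0.23, adjusted p = 0.17) nor Ftl1 (0.14, 0.432) was called. Without control library 2, Cisd1 (adjusted p = 0.0904), Prdx6 (0.126) and Ftl1 (0.131) were not called. As a list they were not called (camera adjusted p = 0.105). Ferroptosis execution had 3 higher and 3 lower of 29 (1 and 3 over the list alone; adjusted p = 0.89): Cybb, a subunit of the phagocyte NADPH oxidase, fell from 6.75 ± 3.44 to 0.22 ± 0.20 CPM, Keap1, the NRF2 inhibitor, was lower (-0.72, SE 0.14), as was Agps (-0.47), and Mdh1 was higher (0.50). Its median (-0.01) and the camera direction (up) differed in sign. In iron handling, 4 of 22 genes were higher and 2 lower (4 and 2 over the list alone; camera adjusted p = 0.915). With the length and GC trend removed, 1 of these 22 was higher and 3 were lower. The iron exporter Slc40a1 (43.6 ± 20.8 to 11.7 ± 1.61 CPM) and Hfe (-1.59, SE 0.23) fell. NRF2 targets had 6 higher and 2 lower of 26 (6 and 2 over the list alone; camera adjusted p = 0.25). The autophagy receptor Sqstm1 (1.00, SE 0.12) and Gstm1 (0.82) rose, and G6pdx (-0.55) and Ephx1 (-1.56) fell.

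**Figure D2:**
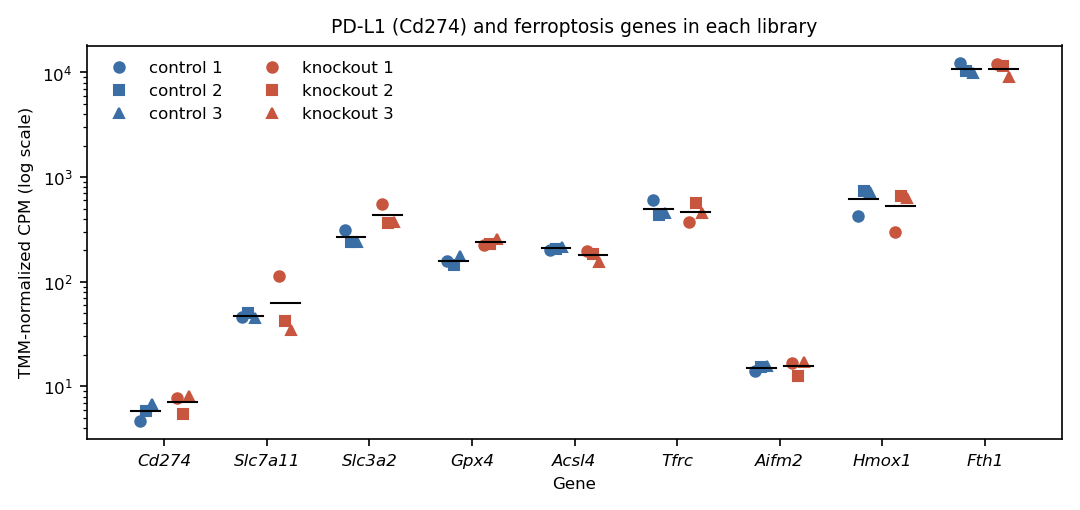
TMM-normalized CPM (log scale) of Cd274 and 8 ferroptosis genes (x axis) in each library, with a line at each group's mean. Slc7a11 is at 113 CPM in knockout library 1 and at 42.0 and 34.3 in the other knockout libraries, and the Cd274 mean is 5.78 in control and 7.08 in knockout.

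Genes of adhesion, of myeloid identity and of interferon and cytokine signalling made up most of the lists that fell. Of 22 tested genes of extracellular matrix and adhesion, 11 were lower and 2 higher (12 and 2 adjusted over the list alone). Its camera adjusted p was 9.98e-05 (adjusted p = 0.476 with an estimated correlation), with the integrin chains Itga6 (23.1 ± 1.13 to 0.48 ± 0.10 CPM), Itgal (10.1 ± 5.09 to 0.47 ± 0.08), Itga4 (143 ± 19.4 to 35.4 ± 14.9) and Itgav (-0.79, SE 0.12) lower. Macrophage and monocyte markers had 6 lower and 1 higher of 16 (7 and 1 over the list alone; adjusted p = 0.0031; adjusted p = 0.476 with an estimated correlation). Lysozyme Lyz2 fell from 111 ± 25.4 to 15.9 ± 4.25 CPM, and the Fc receptor Fcgr1 (-1.18) and the scavenger receptor Cd163 (-2.70) fell too. Ly6c2, with 3 counts in all knockout libraries, had a control-to-knockout ratio of 53.8 (18.4 to 261). Co-stimulatory and checkpoint molecules had 9 lower and 2 higher of 22 (9 and 2 over the list alone; adjusted p = 0.0362; adjusted p = 0.476 with an estimated correlation). Cd24a fell from 68.8 ± 15.5 to 4.84 ± 0.52 CPM, Ceacam1 (-3.13) and Lgals9 (-1.75) fell, and Tnfsf9, a co-stimulatory ligand, rose from 20.6 ± 1.90 to 43.4 ± 2.55. That list was not called without control library 3 (adjusted p = 0.055), knockout library 2 (0.0816) or knockout library 3 (0.0565).

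Type I interferon response genes had 8 lower and 1 higher of 23 (13 and 1 adjusted over the list alone). Its camera adjusted p was 0.00368 (adjusted p = 0.567 with an estimated correlation), with Ifit2 (-1.87), the transcription factor Irf7 (-1.95), Parp14 (-1.84) and Rsad2 (-2.62) lower, each from under 7 CPM in control. The JAK-STAT list had 9 lower and 1 higher of 34 (9 and 2 adjusted over the list alone). Its camera adjusted p was 0.0362 (adjusted p = 0.49 with an estimated correlation), with the interleukin 10 receptor chain Il10ra (-2.25, SE 0.27), Jak2, Csf2ra (-0.84) and Stat5b (-0.72) lower. It was not called without control library 2 (adjusted p = 0.0503), control library 3 (0.0589), knockout library 2 (0.0769) or knockout library 3 (0.0565), nor after the length and GC correction (0.0832; with the replicate block 0.144), but was with chromosome medians removed too (0.0409). In fatty acid synthesis and desaturation, 10 of 27 genes were lower and 0 higher (10 and 0 over the list alone; adjusted p = 0.00749; adjusted p = 0.476 with an estimated correlation). The falls named were those of the lipid uptake and binding genes Cd36 (64.0 ± 22.5 to 13.0 ± 2.04 CPM), Fabp5 (15.4 ± 4.10 to 2.55 ± 1.79) and Fabp4 (-3.33), and of the elongase Elovl7 (-2.16). Dendritic cell markers had 6 lower and 1 higher of 16 (7 and 1 over the list alone) and were not called as a list (adjusted p = 0.105). Btla (-3.22), Cadm1 (-0.79) and Sirpa (-0.43) were lower. Btla had 15, 3 and 1 counts in knockout libraries 1, 2 and 3. Tcf4 was lower (-0.50) before but not after the length and GC correction (0.18, adjusted p = 0.33). Chemokines and their receptors had 3 lower and 0 higher of 12 (5 and 1 over the list alone; adjusted p = 0.223): Cxcl14 (38.7 ± 24.3 to 4.40 ± 2.36 CPM), Cx3cl1 (-2.46) and Cxcr3 (-1.34).

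**Figure D3:**
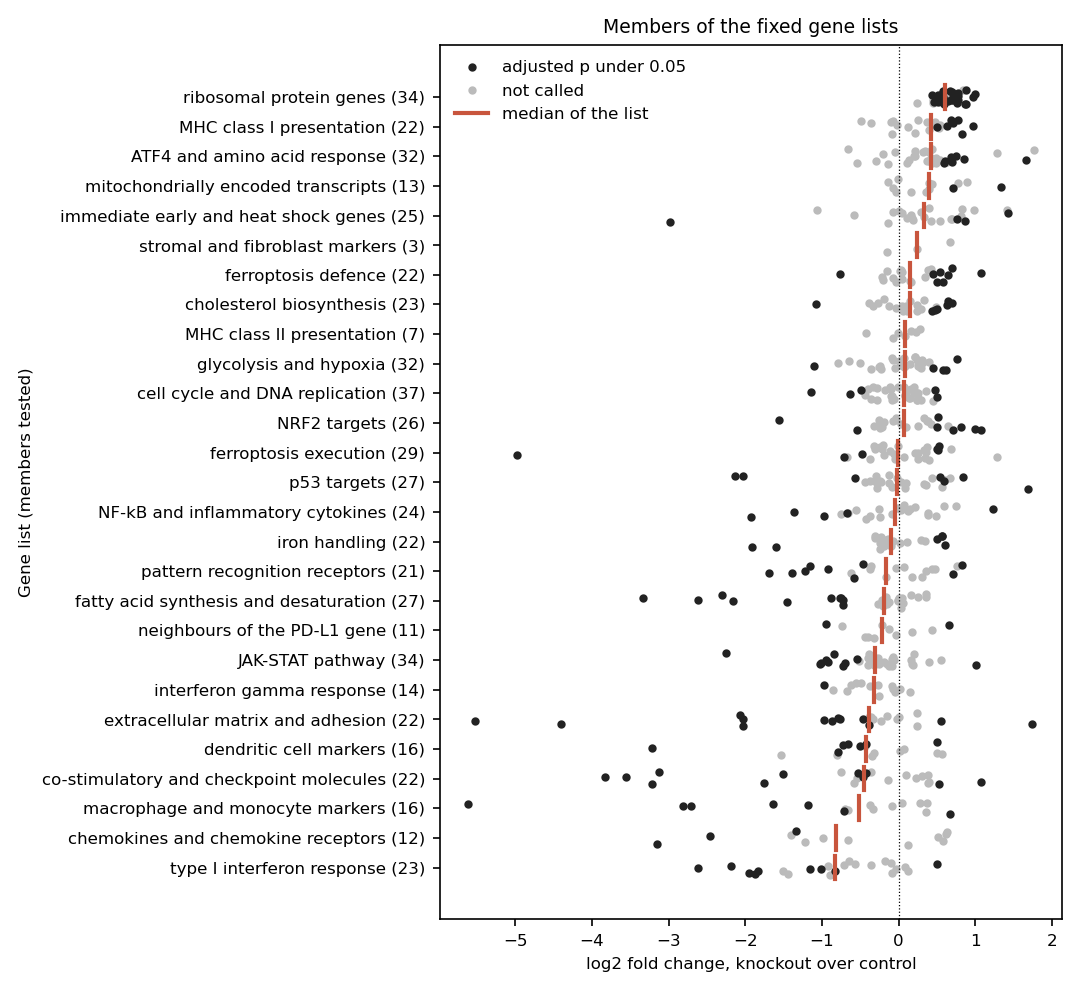
Log2 fold change of each tested member (points; black, edgeR adjusted p under 0.05) of the 27 fixed lists with tested members, with each list's median (bar) and number of tested genes. The ribosomal protein genes have the highest median, 0.61, and the type I interferon response the lowest, -0.83.

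The 3 lists called higher were those of ribosomal protein, class I presentation and amino acid response genes. Of 34 ribosomal protein genes, 25 were higher and 0 lower (32 and 0 over the list alone; median log2 fold change 0.61; camera adjusted p = 5.12e-12; adjusted p = 0.476 with an estimated correlation), with Rps2 at 3981 ± 519 against 2023 ± 254 CPM, and Rpl32 (0.99) and Rpl22 (0.88). After the length and GC correction 12 were higher and the median was 0.40. MHC class I presentation had 7 higher and 0 lower of 22 (8 and 0 adjusted over the list alone). Its camera adjusted p was 0.0031 (adjusted p = 0.476 with an estimated correlation). The immunoproteasome subunit Psmb8 (0.97, SE 0.15) rose, as did the class I genes H2-K1 (0.77), H2-T23 (0.82) and H2-T22 (0.71), whose reads may be shared among related genes. Of its 12 members on chromosome 17, 6 were higher, and of the 10 elsewhere, 1. The whole of chromosome 17 had a median log2 fold change of 0.41, and with length, GC and chromosome medians removed the list was not called (adjusted p = 0.398), the median of its 12 chromosome 17 members going from 0.56 to 0.08. ATF4 and amino acid response genes had 7 higher and 0 lower of 32 (7 and 0 over the list alone; adjusted p = 0.00555; adjusted p = 0.761 with an estimated correlation): Ddit3, a stress transcription factor, went from 7.29 ± 0.29 to 23.3 ± 14.4 CPM, the serine synthesis enzyme Phgdh from 630 ± 47.3 to 1057 ± 27.5, and Atf4 (0.59) and Cebpb (0.60) rose. Without knockout library 1 that list was not called (adjusted p = 0.563).

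Cholesterol biosynthesis had 6 higher and 1 lower of 23 (6 and 2 over the list alone; camera adjusted p = 0.223). Fdft1 (0.63), Ebp (0.64) and Acat2 (0.70) rose. Glycolysis and hypoxia genes had 4 higher and 1 lower of 32 (2 and 0 over the list alone; camera adjusted p = 0.342). Gapdh (0.58), Tpi1 (0.62) and Egln3 (0.45) rose, and P4ha2 (-1.10) fell. Pattern recognition receptors had 2 higher and 7 lower of 21 (4 and 8 over the list alone; camera adjusted p = 0.483). The ATP receptor P2rx7 fell from 51.9 ± 4.04 to 19.8 ± 3.31 CPM and Tlr13 fell (-0.58), while Tlr2 (0.71) and Clec4d (0.83) rose. P53 targets had 4 higher and 3 lower of 27 (4 and 3 over the list alone; camera adjusted p = 0.633). Gdf15 and Bbc3 (0.85) rose, and Trp53inp1 (-2.13) and Btg2 (-2.02) fell. The median (-0.02) and the camera direction (up) differed in sign. Cell cycle and DNA replication had 2 higher and 3 lower of 37 (0 and 3 over the list alone; adjusted p = 0.915; median 0.08, camera direction down): the proliferation marker Mki67 (802 ± 143 to 362 ± 63.2 CPM), Bub1b (-0.64) and Top2a (-0.49) fell and Cdt1 (0.48) rose. NF-kB and inflammatory cytokines had 1 higher and 4 lower of 24 (1 and 4 over the list alone; adjusted p = 0.626), the falls being those of Icam1 (-0.98), Rel (-0.67), Il1rn (-1.36) and Il27 (-1.93).

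Immediate early and heat shock genes had 3 higher and 1 lower of 25 (2 and 1 over the list alone; camera adjusted p = 0.123). Egr1 fell (-2.99, SE 0.51), and Ier3 and Hspe1 (0.86) rose. Of 13 mitochondrially encoded transcripts, 2 were higher and 0 lower (2 and 0 over the list alone; camera adjusted p = 0.105). The call named by the rule was mt-Co2, at 1.33 (SE 0.37). After the length and GC correction 0 were higher (mt-Co2 0.91, adjusted p = 0.157), and the median went from 0.394 to 0.063. With the replicate block added to that correction mt-Co2 was called (1.03, adjusted p = 0.0102). Without the correction it was not called without control library 2 (adjusted p = 0.0878) or knockout library 2 (0.107). The interferon gamma response had Icam1 as its only call among 14 genes (0 higher, 1 lower, and 0 and 1 over the list alone; adjusted p = 0.123). MHC class II presentation had 0 higher and 0 lower of 7 (0 and 0 over the list alone; adjusted p = 0.843). Of 26 stromal and fibroblast markers 3 were tested and 0 called (0 over the list alone; adjusted p = 0.664); in control library 2 Col1a1 had 2235 counts and Fn1 1382, against at most 5 and 3 in any other library. No lymphocyte, epithelial or endothelial marker had enough counts to be tested (174 counts over 25 genes and all libraries, at most 12 in any library). None of the 9 lists called at the preset correlation held with an estimated correlation (0 called).

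Transcript length went with the group. The log2 deviation per doubling of exon length was 0.10, 0.14 and 0.08 in control libraries 1, 2 and 3 and -0.02, -0.17 and -0.13 in knockout libraries 1, 2 and 3 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). With genes in 10 groups by exon length, the shortest group, at a median of 1205 bases, had a median log2 fold change of 0.41, and the longest, at 12348 bases, of -0.44. With each library's length and GC trend removed, these genes named above were no longer called: Atf4 (0.38, adjusted p = 0.0798), Cebpb (0.30, 0.0967), Agps (-0.27, 0.0979), Mdh1 (0.26, 0.109), Egln3 (0.24, 0.161) and Top2a (-0.28, 0.0903). Nor were Bbc3 (0.63, adjusted p = 0.0981), Ebp (0.38, 0.065), Acat2 (0.46, 0.0535), Ier3 (1.00, 0.0583) and Rpl32 (0.57, 0.0523), of which Acat2, Ier3 and Rpl32 were called with the replicate block added.

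**Figure D4:**
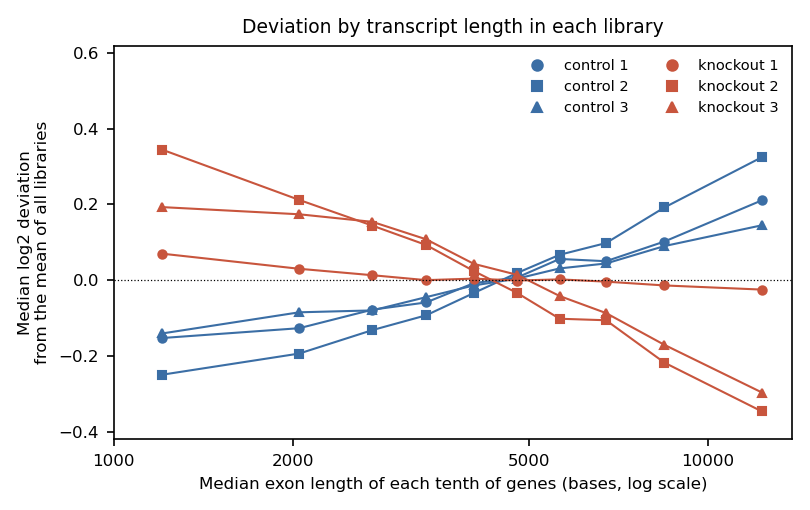
Median log2 deviation from the mean of all libraries (y axis) against the median exon length of 10 groups of genes (x axis, log scale), a line per library. In the longest group the control libraries are at 0.21, 0.33 and 0.15 and the knockout libraries at -0.03, -0.35 and -0.30.

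Whole chromosomes were also shifted. Over 500 genes of chromosome 17 with a mean log2 CPM of at least 2, the median log2 fold change after the length and GC correction was 0.41, with 0.36, 0.43 and 0.41 in knockout libraries 1, 2 and 3 and between -0.01 and 0.01 in the controls. Chromosome 16 had a median of 0.29 and chromosome 18 of -0.22. Smaller medians, of one sign in all 3 knockout libraries, were found among others on chromosomes 1 (0.196), 3 (0.166), 19 (0.135), 4 (0.116), 2 (-0.142), 7 (-0.107) and X (-0.111). On chromosome 19 knockout library 1 (0.048) was not above control library 1 (0.05). Chromosome 6 had a median of 0.22, but its shift was uneven. Its segments of equal size from position 80000001 on had medians between 0.29 and 0.38, above 0 in every knockout library. Earlier segments lay between -0.06 and 0.03. The later stretch, picked out after its values were seen, holds Gapdh, Tpi1, Clec4d, Rpl32 and Clec4a3. Whether that stretch accounts for their rises was not tested. In the first 30 Mb of chromosome 9, a segment chosen after its values were seen, 47 of 88 genes were lower and 0 higher (median -0.56), among them Keap1 and Icam1, against a median of 0.02 for the other 452 genes of that chromosome. Of the 89 genes with a position that were at least 2-fold higher, 31 lay on chromosome 17 (34.8%, against 5.2% of tested genes), a chromosome picked for its shift. Besides the class I presentation genes, Tnfsf9, Rps2, Acat2, Ier3, Arhgdig and Morn2, named above as higher, lie on chromosome 17. The rises given for them above include any shift of the whole chromosome, so they cannot be read as changes of these genes alone.

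**Figure D5:**
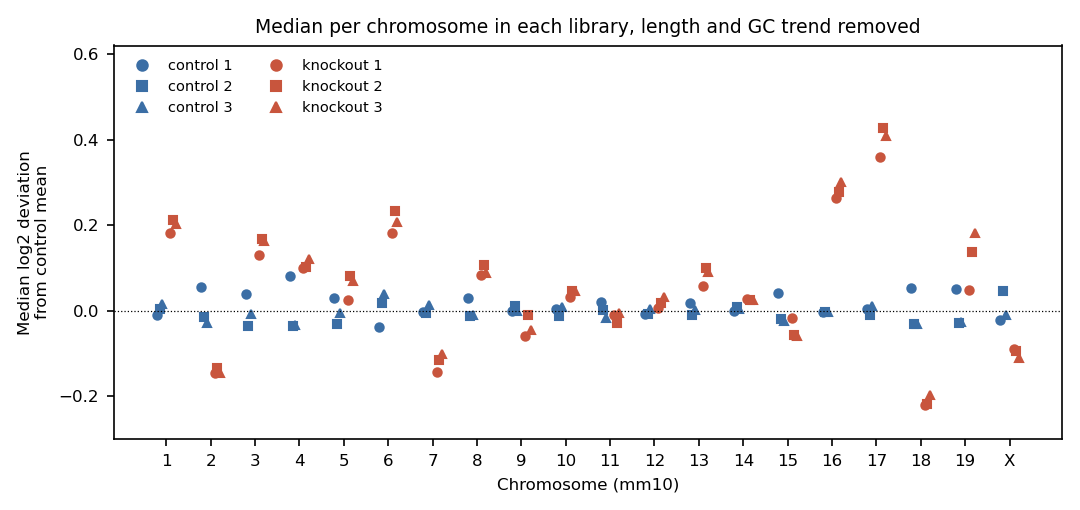
Median log2 deviation from the control mean (y axis) of the genes of each chromosome (x axis) in each library, after each library's length and GC trend was removed. Chromosome 17 lies between 0.36 and 0.43 in the 3 knockout libraries, and chromosome 18 between -0.22 and -0.20.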

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

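The length, GC and chromosome corrections were chosen after the data were seen; the other alternatives were planned. Cd274 stayed uncalled under every alternative. No list called in the main fit changed direction. Among uncalled lists (adjusted p in brackets), MHC class II changed direction without a filter on low counts (0.724) and after the length and GC correction (0.398; with the block 0.326; with chromosomes 0.196). Ferroptosis execution did so under fry (0.9), and stromal and cell cycle genes without a filter (0.226 and 0.813). As single libraries were left out, ferroptosis execution (0.681 to 0.921), iron handling (0.859 to 0.998), stromal (0.414 to 0.976) and cell cycle genes (0.338 to 0.936) changed direction in some fits. Of the 111 genes followed, 48 lost their call without control library 2, 32 without knockout library 2, 25 without knockout library 3, 18 without control library 3, 10 without control library 1 and 0 without knockout library 1, with fewer libraries in each fit; besides Tcf4, 16 lost it after the length and GC correction and 34 with chromosome medians removed too. Of the 111 followed genes, those called in the main fit kept their sign except Tcf4. Tcf4 was at 0.179 with the length and GC correction, 0.18 with the replicate block added and 0.396 with chromosomes. It was not called in any of the 3. Of uncalled genes, log2 fold changes ranged on both sides of 0 with single libraries left out for Slc7a11 (-0.307, without knockout library 1, to 0.723), Tfrc (-0.27 to 0.064), Aifm2 (-0.038 to 0.173), Hmox1 (-0.447 to 0.041) and Fth1 (-0.07 to 0.138). Under total counts alone Aifm2 was at -0.11 and Fth1 at -0.133, and Fth1 was at -0.007 with upper quartile scaling and -0.108 with the length and GC correction (with the block -0.117; with chromosomes -0.189). Genes higher numbered 667 under total counts alone and 751 with chromosomes removed, when 995 were lower, and ranged from 166 (without control library 2) to 2346 (without knockout library 1) as single libraries were left out. Genes lower ranged from 472 to 2616 and those changed at least 2-fold from 410 to 1353, in the fits without the same libraries; glmTreat called 342. Whether the replicate numbers pair the libraries was not settled. Correlations of deviations were 0.15, -0.06 and 0.36 for libraries of the same number and between -0.32 and 0.14 for the others. The replicate block gave 1480 higher and 1732 lower. With an estimated correlation 0 lists were called: adjusted p was 0.476 for the MHC class I, co-stimulatory, macrophage, fatty acid, matrix and ribosomal lists, 0.49 for JAK-STAT, 0.567 for type I interferon and 0.761 for ATF4. The macrophage list went uncalled with an estimated correlation of -0.051, below the preset 0.01. These values therefore do not decide whether correlation between genes produced the calls. Fry called 14, among them ferroptosis defence (0.016), NRF2 (0.0122), interferon gamma (0.04), chemokines (0.0394), dendritic cell (0.0271), cholesterol (0.00143) and glycolysis (0.0289), but neither ATF4 (0.303) nor type I interferon (0.0797). Without a filter on low counts, ferroptosis defence (0.0171), mitochondrial transcripts (0.0171) and immediate early genes (0.0272) were called, the last 2 also with the block (0.0107 and 0.0472). Chemokines were called after the length and GC correction (0.029; with the block 0.000415; with chromosomes 0.0409), and JAK-STAT was not (0.0832; with the block 0.144), nor was MHC class I with chromosomes removed (0.398). Co-stimulatory molecules were not called under total counts alone (0.0522), the 1 CPM filter (0.053) or limma-voom (0.1). Leaving out single libraries, adjusted p ranged from 4.53e-05 to 0.563 for ATF4 (lost without knockout library 1), 0.0335 to 0.265 for interferon gamma, 0.0421 to 0.472 for chemokines (both gained without control library 1), 0.0217 to 0.0816 for co-stimulatory molecules, 0.0227 to 0.0769 for JAK-STAT, 0.0358 to 0.173 for dendritic cell markers, 0.0101 to 0.245 for mitochondrial transcripts and 0.000176 to 0.406 for immediate early genes. The causes of these changes were not tested. For the 4 of 54 lost genes with 0 counts in every knockout library, a fall can be given only as a bound.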

Other observations

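Control library 2 held far more of some transcripts than the other libraries. By a rule chosen after the data were seen (at least 30 counts, and a CPM over 8 times the highest of the other libraries plus 0.1), 48 genes were picked out in it and 0 in each of the other 5 libraries, and the 48 took 0.057% of its counts. Among them were the collagen Col1a1 (2235 counts, and at most 5 in any other library), fibronectin Fn1 (1382, at most 3), the tropomyosin Tpm2 (354), Ccn1 (222), the homeobox genes Hoxc6 (169) and Prrx1 (167), fibrillin Fbn1 (116), tenascin Tnc (113) and Sparc (103). Of the 26 fixed stromal and fibroblast markers, 4 were among these 48 genes, while Col1a2 had 22 counts there, Col3a1 10, and Dcn, Lum and Thy1 0. Of the 48, 5 were tested: Marcks was called (log2 fold change -6.21), and Il31ra, Cavin1, B020010K11Rik and Cdh11 were not. The genes named in this paragraph were chosen after their values were seen, and the source of these transcripts was not tested.

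Tests below of chromosome shifts and of founder cells were written after their values had been seen. Those of the length trend on ribosomal and nearly lost genes, of deleted segments and of other splits were written before their own values were seen. The rule for nearly lost genes and the length and GC correction were themselves set after the data were seen, so tests that use them were not fixed in advance of the data. Of the 10 splits of the 6 libraries into 3 and 3, the real split called 2896 genes and the highest other 0, and 783 and 0 at 2-fold or more. For gene lists the real split called 9 and the highest other 10, and 4 splits called as many as 9. With 10 splits no share can fall under 0.05.

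Short transcripts were higher and long ones lower in the libraries labelled knockout, and a candidate explanation is a difference in RNA integrity or library preparation. Removing each library's length and GC trend took the median of the ribosomal protein genes from 0.61 to 0.395, between the bounds set for either answer. The trend and the knockout label cannot be told apart for these genes, since the trend separates the same libraries as the groups do, and a biological shift of short transcripts stays open.

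The shift of whole chromosomes may come from a difference in copy number between the lines. A length and GC trend as its whole cause is argued against by the chromosome 17 median, 0.408 before and 0.405 after that trend was removed. Chance placement of genes one by one is argued against by 10000 shuffles of the chromosome labels, which gave 1e-04, the smallest value they can give. The shuffles treat genes as independent, and the chromosome was picked for its shift. Chromosome 11, at a median of 0, passed the same shuffle test (Benjamini-Hochberg adjusted p = 0.00083), so a pass does not mean a large shift. Every 10 Mb bin of chromosome 17 with at least 20 genes (8 bins) was above 0 in every knockout library (0.234 or more), but the chromosome was picked for its shift, so this does not decide on copy number. Its genes in 3 groups by expression were at 0.259, 0.41 and 0.517 from low to high, wider apart than the 1.5 times set for copy number, DNA was not measured, and whether the shift came with the knockout or with growth of a separate line was not tested.

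The 54 genes nearly lost in every knockout library may reflect the knockout, or the few cells from which a line is grown. A length and GC trend is argued against by its size: medians of the 10 groups by exon length lay between -0.44 and 0.41, far less than an 8-fold change. With the trend removed, 53 of the 54 stayed past the threshold at 8-fold or more, which a trend of that size could hardly have altered. Deletion of whole segments is argued against by the 108 nearest tested genes, whose median log2 fold change was -0.092. A control culture of mixed cells would allow complete losses but limited gains. The highest gain of a called gene, a log2 fold change of 3.61, was above the 8-fold bound set for it, so that prediction was not met. Gains were not as frequent as losses either, with 140 genes lower by 8-fold or more against 1 higher. That imbalance had been seen before the test was written, so it lends the explanation of few founder cells no support. That explanation cannot be told apart from an effect of the knockout, since the labels name a single knockout derivative.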
